A study of Mus musculus with 13 samples.

How the data were processed

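Poly-A selected, paired-end RNA libraries (Illumina NovaSeq) were made from uterine implantation sites on a control diet (7 libraries) or an obesogenic diet (6 libraries), on day 18.5 of pregnancy, per the labels' protocols. Each library has its own title number, and no litter, batch or day is given. Libraries were taken as separate animals from those titles; the labels do not say so outright, so p-values measure the spread between these libraries. Replicate numbers name libraries in deposition order, are not shared by design and pair nothing.

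The deposited table holds 1 estimated count (expected count) per gene and library, made by the authors and not scaled. Between 70.1% and 73.7% of a library's values were whole numbers to within 1e-06, and the rest were fractional. The submitters' processing notes name STAR 2.7.8a, genome build mm39 and DESeq2, without roles. The program that turned alignments into counts, its strand setting and its handling of shared reads are not given in the sources used here. Reads of near-identical genes (prolactin, Psg, H2-Q, kallikrein and globin families) may therefore be split among copies, and reads of overlapping antisense genes cannot be told apart. Gene names and coordinates come from the deposited table. Its starts count from 0, since stop minus start equalled the gene length for 28563 of 29038 genes also in GENCODE M21, so 1 was added to each start; no coordinate of that older build was used.

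Estimated counts were rounded to whole numbers. Of 29198 genes, 2 were at 0 in every library, and 18436 passed edgeR's filterByExpr with its minimum count of 10. Libraries were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, R 4.3.3) with diet as the only term. Adjusted p-values are Benjamini-Hochberg over all tested genes, and the standard error is the log2 fold change divided by the square root of F. The biological coefficient of variation was 31.1%. CPM values are TMM-scaled with no prior, log2 CPM used a prior count of 2, and group errors are SD between libraries.

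The comparison, its tests, 34 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were, among called genes with mean log2 CPM of at least 0, the 10 largest increases, the 10 largest decreases and the 10 smallest p, passing over unnamed models and pseudogenes, with up to 4 members of each list by smallest p and 12 genes fixed in advance. Lists with at least 4 tested members, 33 of them, were tested with camera (limma 3.58.1, preset correlation 0.01, 2-sided, adjusted over lists) and again with an estimated correlation. Counts adjusted over the list alone are given beside counts over all genes. Marker lists cover trophoblast, decidua, yolk sac and fetal liver, endothelium, epithelium, adipocytes, blood and immune cells, since the tissue could hold these. A list score is the mean log2 CPM of its members.

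Tested on simulated counts with the means, dispersions and totals of these libraries (18109 genes, 200 of them changed), the fit recovered 14% of genes changed 1.5-fold, 46% at 2-fold, 82% at 4-fold and 94% at 8-fold, with 3 false calls among 121. With the trophoblast score in the model it recovered 0%, 12%, 68% and 78%, with 4 false calls among 83. Small changes can therefore go uncalled at this number of libraries. Each gene was drawn independently and without relation to that score. Variation that genes share in the real libraries is therefore not in these rates.

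Libraries were compared in pairs over 8469 genes. The closest pair with a value, obesogenic replicates 3 and 4, still differed by 4.2 times the sampling noise. For control replicates 4 and 6 this measure gave no value. Their log2 CPM correlated at 0.9345, against 0.9878 for obesogenic replicates 3 and 4. No library was therefore counted as a copy of another. The alternatives were DESeq2 1.42.0, limma voom with sample weights, RLE and upper-quartile scaling, no filter or a stricter filter, a threshold of 0.1, a trophoblast score or 1 surrogate variable (sva 3.50.0) in the model, leaving out the 2 libraries whose title numbers belong to another series, and leaving out each library in turn. Leaving out 3 libraries high in yolk sac markers, decidua and yolk sac scores in the model, and thinning to the smallest total were added after the data were seen. The 2 libraries with title numbers of another series are control replicate 1 and obesogenic replicate 1. Only their numbers set them apart, and no label places them in another cohort or batch. The alternative for a table without counts was not needed. Figures were drawn with matplotlib 3.10.9.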

Results

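The series measured messenger RNA in the uterus of pregnant mice on either a control diet or an obesogenic diet, a diet meant to produce obesity. Females ate the diet for 10 weeks and then through pregnancy, and tissue was taken on day 18.5, at term but before labour. Each library came from 1 implantation site, after the fetus, placenta and amnion had been taken away. The comparison asks how diet-induced obesity alters gene expression in the term uterus. There were 7 control and 6 obesogenic diet libraries. Their total estimated counts ran from 10785912 to 15553855, with means of 13.45 ± 1.86 M (SD, n = 7) for control and 13.01 ± 1.5 M (SD, n = 6) for obesogenic diet. This difference of -0.442 M lay within the spread between libraries (exact permutation test over all 1716 splits, 2-sided, p = 0.645). Without obesogenic replicate 3 it was 0.00318 M. All levels are CPM, counts scaled to the size of the library, and positive log2 fold changes are higher under the obesogenic diet, with their standard error.

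Uteri of the obesogenic diet group carried more RNA of single genes of trophoblast (5 of 9 tested), matrix proteases and their inhibitors (9 of 18), interferon response (5 of 19) and blood vessel endothelium (4 of 15). As whole lists these passed only with a preset correlation between genes, at an adjusted p = 0.304, 0.304, 0.618 and 0.338 with an estimated correlation, and the interferon list turned lower with a trophoblast score in the model (0.718). Lists of uterine epithelium, oestrogen response and the mitochondrial respiratory chain leaned lower with the preset correlation, at an adjusted p = 0.643, 0.304 and 0.618 with an estimated correlation. Of their members 0 of 18, 1 of 14 and 1 of 23 were called singly. Of 18436 genes tested with edgeR's quasi-likelihood test, 791 were higher and 319 lower in the obesogenic group at a Benjamini-Hochberg adjusted p under 0.05. At least 1 log2 unit separated the groups for 413 of the higher genes and for 132 of the lower ones. Unnamed gene models and pseudogenes made up 119 of these 1110 genes. Without obesogenic replicate 1 the counts were 431 higher and 137 lower. The lower genes numbered 183, 178 and 184 without control replicates 3, 4 and 5, and 209 and 161 without obesogenic replicates 4 and 5. DESeq2 called 1176 higher and 700 lower, and limma voom 886 and 516. Control replicate 1 and obesogenic replicate 1 have title numbers in another range, and without both there were 438 and 176. Leaving out control replicate 1 alone gave 773 and 353, whereas leaving out obesogenic replicate 1 alone already gave counts as low. With the trophoblast score in the model edgeR called 0 higher and 0 lower (756 at an unadjusted p under 0.05), and with a decidua score 300 and 158. The contraction genes Oxtr and Gja1 did not pass the test.

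The 10 named genes with the smallest p were Pltp, Gpr176, Phospho1, H2-Q7, H2-Q6, Mgp, Cpm, Rnf150, H2-Q4 and Kif21b. Pltp, which transfers phospholipids between lipoproteins and lies on chromosome 2 at 164681439 to 164699632 (mm39, ENSMUSG00000017754), rose from 164 ± 35.7 CPM (SD, n = 7) to 688 ± 252 CPM (SD, n = 6). Its log2 fold change was 2.07 ± 0.22 (adjusted p = 0.00156), with all 6 obesogenic libraries above every control library. Mgp, an inhibitor of calcification, rose by 2.43 ± 0.29, and Phospho1, a phosphatase of mineralising tissue, by 2.56 ± 0.30. The receptor gene Gpr176 rose by 2.46 ± 0.29 and the kinesin gene Kif21b by 1.53 ± 0.19. Cpm, which encodes carboxypeptidase M (chromosome 10, 117465406 to 117523258, ENSMUSG00000020183), fell from 109 ± 40.5 CPM (SD, n = 7) to 28.4 ± 5.57 CPM (SD, n = 6). Rnf150, a ring finger gene, changed by a smaller -0.65 ± 0.08 at the same adjusted p of 0.00156. Each of these genes passed the test whichever single library was left out. With a trophoblast marker score in the model, Pltp stood at 1.39 ± 0.40 (adjusted p = 0.998, with 7.4e-16 the lowest of its alternatives) and Cpm at -1.75 ± 0.36 (adjusted p = 0.555, lowest 6.77e-13).

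By size, the largest increase among named genes was that of Prl2a1. This placental prolactin-family gene (chromosome 13, 27985638 to 27992713, ENSMUSG00000022886) rose by 4.73 ± 1.08, from 6.13 ± 12.0 CPM (SD, n = 7) to 166 ± 160 CPM (SD, n = 6). Without obesogenic replicate 5 its adjusted p was 0.0525. Fnd3c2 rose by 4.64 ± 0.89, Taf7l by 4.60 ± 0.82, the oestrogen sulfotransferase gene Sult1e1 by 4.59 ± 0.94 and Sct, which encodes secretin, by 4.54 ± 0.85. Psg22, Prl7b1, Prl2c5, Prl7d1 and Fthl17a followed at 4.46 ± 0.84, 4.45 ± 0.98, 4.32 ± 0.99, 4.31 ± 0.83 and 4.24 ± 0.92. Leaving out obesogenic replicate 5 took Prl7b1 to an adjusted p of 0.0501 and Prl2c5 to 0.0584. Prolactin-family and Psg genes have near-identical copies, so reads can be shared among them and the values of single members are uncertain.

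The largest decrease among named genes was that of Abcb5. This transporter gene (chromosome 12, 118831560 to 118930157, ENSMUSG00000072791) fell from 2.14 ± 1.20 CPM (SD, n = 7) to 0.0503 ± 0.0912 CPM (SD, n = 6). Its fitted change was -5.14 ± 0.69 (adjusted p = 0.00202), and it was near the detection floor in the obesogenic group. Alox12e and Alox15, lipoxygenase genes on chromosome 11, changed by -4.86 ± 0.97 and -3.51 ± 0.66. The keratin gene Krt4 changed by -2.82 ± 0.57, Obp2a by -2.93 ± 0.62, Syt6 by -2.70 ± 0.60 and Dpysl5 by -2.61 ± 0.49. Kallikreins Klk1b24 and Klk1b21, which are close paralogs, changed by -2.75 ± 0.64 and -2.61 ± 0.67, and the serine protease gene Tmprss11a by -2.47 ± 0.62. Klk1b24 had an adjusted p of 0.055 without obesogenic replicate 5. Klk1b21 lost its call in 9 of the 13 fits that left out 1 library (highest adjusted p = 0.0704), and Tmprss11a in 4 of them (highest 0.0778).

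**Figure D1:**
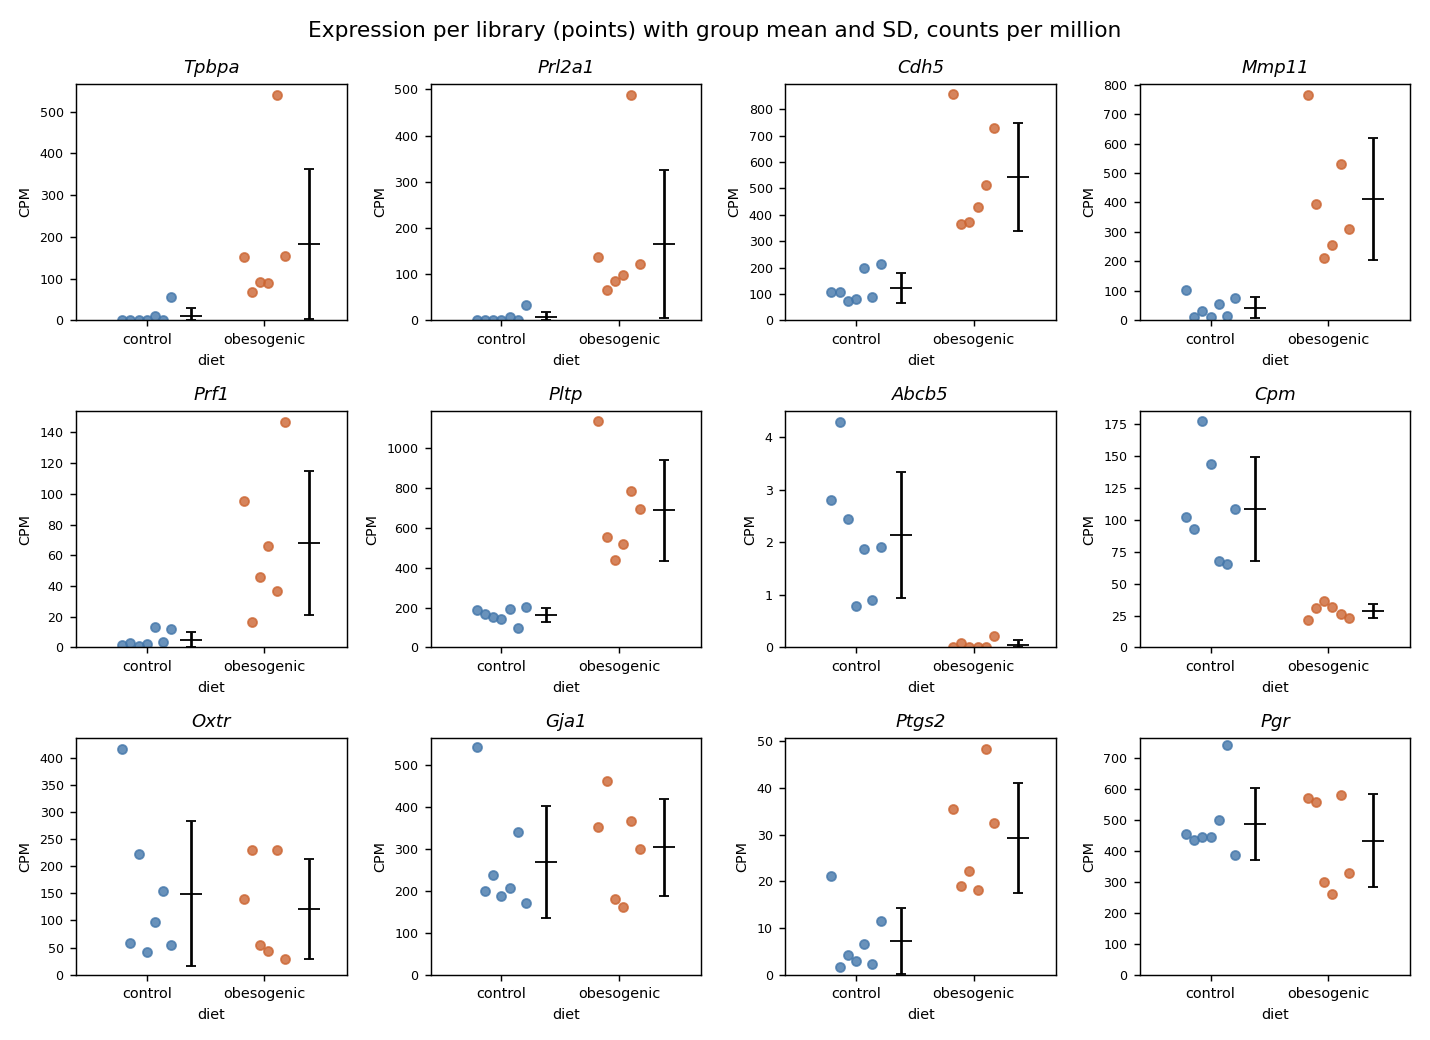
Level of 12 genes in each library in CPM (vertical axis, linear from 0), with control libraries in blue and obesogenic libraries in orange; black bars give the group mean and SD (n = 7 and n = 6), ending at 0 where the SD exceeds the mean. All 6 obesogenic libraries lie above every control library for Tpbpa, Prl2a1, Cdh5, Mmp11, Prf1 and Pltp and below every control library for Abcb5 and Cpm, while the groups overlap for Oxtr, Gja1, Ptgs2 and Pgr.

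Trophoblast and placenta markers were the list that moved furthest. Of its 9 tested genes 5 rose, 7 when adjusted over the list alone, none fell, and the median log2 fold change was 3.48. Another 10 of its 19 measured members had too few counts to test, and they are not in that median. Summed over libraries, Prl3b1 had 144 counts in control libraries, 136 of them in a single library, and 126 in obesogenic libraries, Psg17 45 and 49, Syna 33 and 23, Prl5a1 2 and 27, and Prl7a1 1 and 28. The list was higher by camera (adjusted p = 2.3e-09), and its adjusted p was 0.304 with an estimated correlation. Plac1, a placental gene, rose by 3.86 ± 0.82. Tpbpa, a spongiotrophoblast marker, rose by 4.16 ± 1.10 from 10.1 ± 20.1 CPM (SD, n = 7) to 183 ± 179 CPM (SD, n = 6). Its call was lost in 11 of the 13 fits without 1 library (highest adjusted p = 0.0992). The score of the list, its mean log2 CPM, was -0.24 ± 1.88 (SD, n = 7) in control and 3.97 ± 0.88 (SD, n = 6) in obesogenic libraries. Control replicate 7 reached 3.62, above the 2.85 of obesogenic replicate 2. Of the variance of this score, 69.6% lay between the diet groups.

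Among decidua markers, 2 of 10 tested genes rose: Htra3, a serine protease gene, by 1.16 ± 0.18 and the angiopoietin gene Angpt4 by 1.33 ± 0.32. Angpt4 had an adjusted p of 0.0582 without control replicate 3 and 0.0732 without obesogenic replicate 1. The list median of -0.16 and its mean of 0.24 differ in sign, and camera put it upward without passing (adjusted p = 0.526). Over the list alone 3 members were higher and 2 lower. In the yolk sac and fetal liver list, 1 of 11 tested genes rose, the retinol carrier Rbp4 (2.93 ± 0.78, adjusted p = 0.0432), and its call was lost in 12 of the 13 fits without 1 library. The list median was 0.81 (camera adjusted p = 0.713). Its score stood apart in control replicate 7 (8.59) and obesogenic replicates 3 (8.38) and 4 (8.94), against at most 5.75 in the other 10 libraries. The 4 Y-linked genes fell under the count filter and were not tested.

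**Figure D2:**
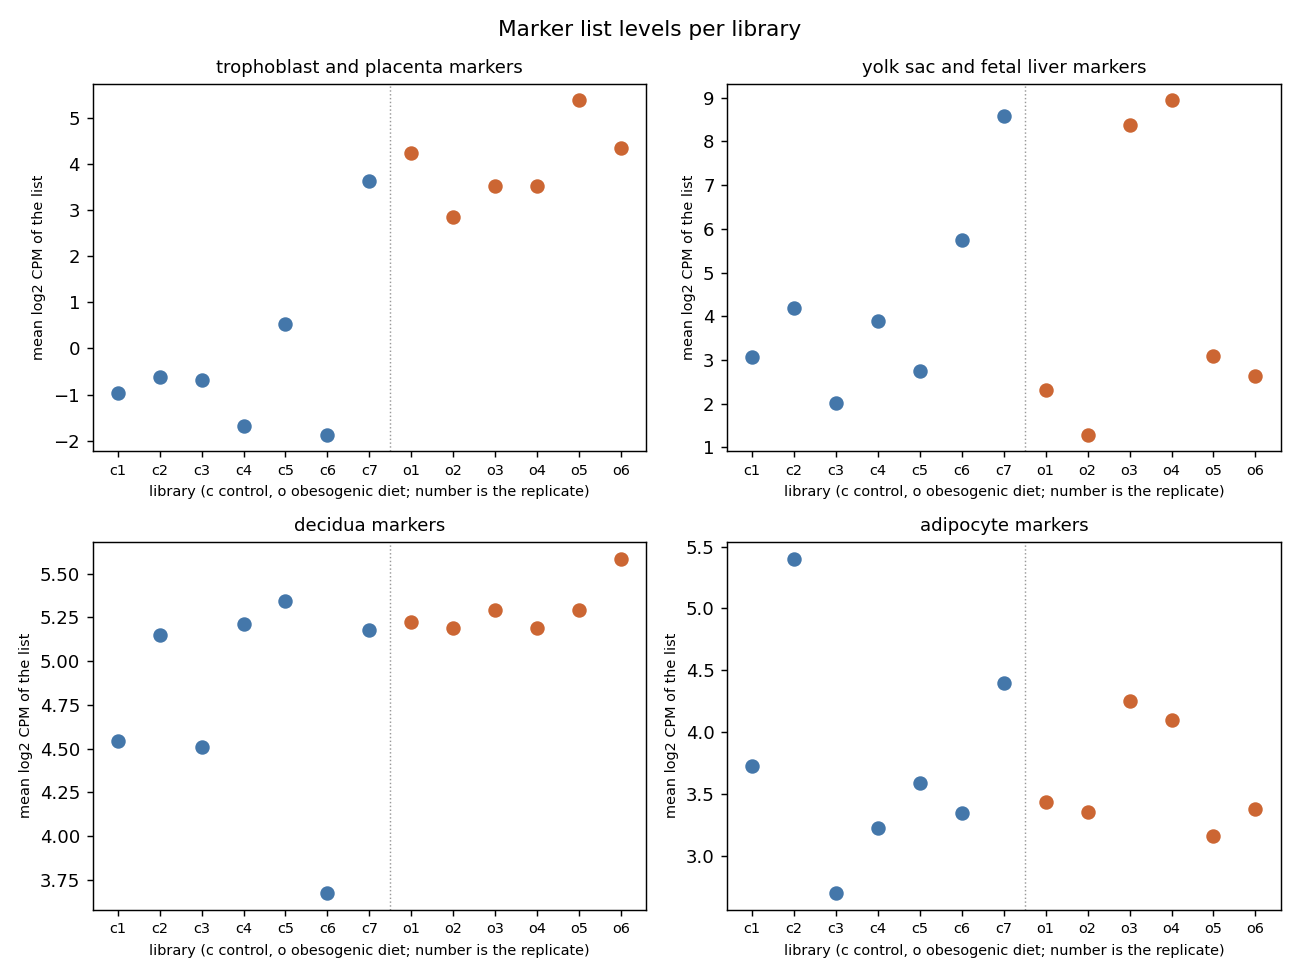
Mean log2 CPM of 4 marker lists (vertical axes) in each of the 13 libraries (horizontal axes; control libraries c1 to c7 in blue, obesogenic libraries o1 to o6 in orange). The trophoblast score is between 2.85 and 5.37 in every obesogenic library and reaches 3.62 in control replicate 7; the yolk sac score is highest in control replicate 7 and obesogenic replicates 3 and 4; the adipocyte score is highest in control replicate 2.

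Endothelial markers rose as a list (median 0.58, camera adjusted p = 2.31e-07; adjusted p = 0.338 with an estimated correlation). Of 15 tested members, 4 rose over all genes and 11 when adjusted over the list alone. Cdh5, the junction cadherin of vessel walls, rose from 124 ± 56.8 CPM (SD, n = 7) to 544 ± 204 CPM (SD, n = 6), by 2.14 ± 0.30 (adjusted p = 0.00239). The growth factor receptor gene Flt1 rose by 1.55 ± 0.29, Cldn5 by 0.81 ± 0.20 and Pecam1 by 0.58 ± 0.16. Cldn5 lost its call in 6 of the 13 fits without 1 library (highest adjusted p = 0.0826) and Pecam1 in 7 (highest 0.126). The endothelial list's adjusted p was 0.000237 with the trophoblast score in the model and the preset correlation, whereas Cdh5 stood at 0.98 ± 0.41 (adjusted p = 0.998, lowest of its alternatives 3.14e-10).

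Matrix proteases and their inhibitors rose as a list as well (median 0.71, camera adjusted p = 2.08e-06; adjusted p = 0.304 with an estimated correlation). Of 18 members 9 rose and 1 fell, or 10 and 2 adjusted over the list alone. Mmp11, which encodes stromelysin-3, rose from 42.8 ± 35.8 CPM (SD, n = 7) to 411 ± 207 CPM (SD, n = 6), by 3.26 ± 0.57. The membrane-bound protease gene Mmp14 rose by 1.63 ± 0.23 and the protease inhibitor gene Serpine2 by 1.52 ± 0.29, whereas the gelatinase gene Mmp9 fell (-1.34 ± 0.25). Under the trophoblast score and the preset correlation the list had an adjusted p of 0.00085. Fibrillar collagen and matrix genes did not pass as a list (median -0.47, camera adjusted p = 0.097). Over all genes 3 of 26 rose, Col12a1 by 1.96 ± 0.31, the collagen cross-linking enzyme gene Lox by 1.15 ± 0.25 and Fbln5 by 0.88 ± 0.17. Adjusted over the list alone, 4 were higher and 10 lower. The list passed as lower, with the preset correlation, without control replicate 1 (adjusted p = 0.0161), control replicate 3 (0.0427) or obesogenic replicate 5 (0.0103). Over all libraries its adjusted p = 0.788 with an estimated correlation.

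Interferon response genes rose as a list (median 0.47, camera adjusted p = 3.38e-06; adjusted p = 0.618 with an estimated correlation). Of 19 members 5 rose, 9 over the list alone, and none fell. Ifit2 rose by 1.37 ± 0.32 and Mx2 by 1.20 ± 0.27. Without obesogenic replicate 1 the adjusted p of Ifit2 was 0.0608 and that of Mx2 0.053. Ifit3, at 1.30 ± 0.31, lost its call in 5 of the 13 fits without 1 library, and Ifit1, at 1.35 ± 0.36, in 8. Among class I antigen-presentation genes, H2-Q7 rose by 2.38 ± 0.28, H2-Q6 by 2.55 ± 0.30 and H2-Q4 by 1.61 ± 0.19; these are close paralogs whose reads can be shared. The interferon list turned downward without passing (adjusted p = 0.718) with the trophoblast score in the model.

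T and NK cell markers passed as a list (median 0.63, camera adjusted p = 0.0264; adjusted p = 0.643 with an estimated correlation). Of its 8 tested genes 2 rose, both encoding proteins of cytotoxic granules. Its other 8 members had too few counts to test, among them Klrb1c (52 counts summed over control and 13 over obesogenic libraries), Ncr1 (27 and 16), Gzma (13 and 3), Trac (39 and 59) and Klrd1 (24 and 41). Prf1, for perforin, rose from 5.14 ± 5.25 CPM (SD, n = 7) to 67.9 ± 47.0 CPM (SD, n = 6), by 3.71 ± 0.67, and Gzmb by 2.52 ± 0.60. Gzmb had an adjusted p of 0.0599 without obesogenic replicate 1 and 0.055 without obesogenic replicate 6. The T cell receptor component genes Cd3g (0.71 ± 0.46) and Cd3e (0.63 ± 0.44) did not pass. The list call was lost without control replicate 1 (adjusted p = 0.096), control replicate 6 (0.0643), obesogenic replicate 5 (0.0645) or obesogenic replicate 6 (0.0655), and with the trophoblast score (0.493). Macrophage markers passed as lower (median -0.44, camera adjusted p = 0.0177; adjusted p = 0.741 with an estimated correlation). None of the 14 members passed over all genes, and 1 higher and 4 lower did so over the list alone. Csf1r was at -0.44 ± 0.13 and Cd68 at 0.49 ± 0.17. This call was lost without control replicate 2 (0.0789), control replicate 4 (0.052) or obesogenic replicate 4 (0.0765), and with the trophoblast score (0.201).

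Inflammatory cytokines and chemokines did not pass (median -0.13, camera adjusted p = 0.805). The cytokine gene Il1a was the 1 of 13 that changed, falling in the obesogenic group (-1.75 ± 0.42). It lost its call without obesogenic replicate 1 (adjusted p = 0.0696), 4 (0.0565) or 5 (0.0593). None of the 5 tested neutrophil markers passed (median -0.56, camera adjusted p = 0.668), with Lcn2 at -0.89 ± 0.58 (-0.06 without control replicate 1). Nor did any of the 5 tested B cell and plasma cell markers (median -0.40, camera adjusted p = 0.713), with Ighm at -0.47 ± 0.19. Red cell markers had no called gene among 5 (median -0.57, camera adjusted p = 0.971), with Hba-a1 at -0.57 ± 0.68 (0.23 ± 0.67 by limma voom).

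Contraction-associated proteins showed no list difference (median 0.05, camera adjusted p = 0.526). Oxtr, the oxytocin receptor gene, had 150 ± 134 CPM (SD, n = 7) in control and 121 ± 92.7 CPM (SD, n = 6) in obesogenic libraries, a log2 fold change of -0.31 ± 0.62 (adjusted p = 0.829), and 0.20 ± 0.58 without control replicate 1. Gja1, which encodes the gap junction protein connexin 43, was at 0.17 ± 0.31 (adjusted p = 0.8; between 0.01 and 0.44 with 1 library left out), and the prostaglandin F receptor gene Ptgfr at -0.27 ± 0.60 (adjusted p = 0.847; 0.20 ± 0.57 without control replicate 1). Of 17 tested members 1 rose, Ptgs2, which encodes the inducible cyclooxygenase, by 2.01 ± 0.52 (adjusted p = 0.0369). That call was lost in 8 of the 13 fits without 1 library (highest adjusted p = 0.0879). Over the list alone 2 members were higher. Prostaglandin genes as a list did not pass (median 0.02, camera adjusted p = 0.668), with 2 of 21 higher, Ptgs2 and the prostaglandin D synthase gene Ptgds (3.08 ± 0.66).

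Smooth muscle contractile genes leaned lower together, with all 20 members negative and none called singly. The list had a median of -0.37 (camera adjusted p = 0.00111; adjusted p = 0.741 with an estimated correlation). Actg2, a smooth muscle actin gene, was at -0.50 ± 0.24 and Myl9 at -0.48 ± 0.23. Without obesogenic replicate 6 the list adjusted p was 0.0655, and with the trophoblast score its direction turned (0.718). Potassium channel genes did not pass (median -0.35, camera adjusted p = 0.0945). Kcnj2, an inward rectifier, was the 1 of 18 that rose (1.27 ± 0.31), and it lost its call without control replicate 3 (adjusted p = 0.0586) or obesogenic replicates 1 (0.0729) or 4 (0.0565). Kcnma1 was at -0.48 ± 0.30 and Kcnt2 at 0.01 ± 0.23, between -0.10 and 0.13 with 1 library left out. That list passed as lower, with the preset correlation, without control replicate 3 (0.0127) or obesogenic replicate 5 (0.0256), and over all libraries its adjusted p = 0.788 with an estimated correlation. Sodium, calcium and chloride channel genes did not pass (median -0.09, camera adjusted p = 0.713), with 1 of 25 higher and 2 lower. The sodium channel gene Scn7a rose by 2.16 ± 0.33, Trpm4 changed by -0.49 ± 0.10 and Cacna1d by -0.75 ± 0.15, while the sodium leak channel gene Nalcn was at 0.35 ± 0.34.

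Oestrogen response genes were lower as a list (median -0.61, camera adjusted p = 0.00245; adjusted p = 0.304 with an estimated correlation). Greb1, a target of the oestrogen receptor, was the 1 of 14 called, at -0.89 ± 0.20 (adjusted p = 0.017), and 2 members were lower over the list alone. The receptor gene Esr1 was at -0.34 ± 0.14 (adjusted p = 0.178). With the trophoblast score the list had an adjusted p of 0.157. Uterine epithelium markers were lower as a list (median -0.62, camera adjusted p = 0.000238; adjusted p = 0.643 with an estimated correlation) with none of 18 called singly. Its score was lowest in obesogenic replicates 5 (4.46) and 1 (4.68), while obesogenic replicates 3, 4 and 6 (6.45, 6.5 and 6.44) lay near the control mean of 6.43 ± 0.41 (SD, n = 7). Epcam was at -0.79 ± 0.35 and Grhl2 at -0.72 ± 0.30. Under the trophoblast score and the preset correlation the adjusted p of the epithelium list was 0.0102. Progesterone signalling genes did not pass (median 0.07, camera adjusted p = 0.655), and Pgr was at -0.17 ± 0.22 (adjusted p = 0.709; between -0.27 and -0.04 with 1 library left out). Its 1 called gene of 16, the coactivator gene Ncoa1 at -0.29 ± 0.08, lost its call in 10 of the 13 fits without 1 library (highest adjusted p = 0.0998).

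Mitochondrial respiratory chain genes were lower by a small amount (median -0.21, camera adjusted p = 4.41e-05; adjusted p = 0.618 with an estimated correlation). Of 23 tested members 22 were negative, 1 was called over all genes and 5 over the list alone. That gene, Ndufb8 of complex I, was at -0.47 ± 0.12, and its call was lost in 8 of the 13 fits without 1 library (highest adjusted p = 0.0772). With the trophoblast score in the model and the preset correlation, the list's camera adjusted p was 0.000748. No list was tested with that score and an estimated correlation together. Cholesterol synthesis and uptake genes were higher as a list (median 0.34, camera adjusted p = 0.00111; adjusted p = 0.643 with an estimated correlation), with 2 of 21 called. Abca1, which exports cholesterol, rose by 1.39 ± 0.20, and Dhcr7, of cholesterol synthesis, by 0.62 ± 0.14, with an adjusted p of 0.0524 without obesogenic replicate 1. The list stood at 0.784 with the trophoblast score. ER stress and amino acid response genes were higher (median 0.20, camera adjusted p = 0.00715; adjusted p = 0.643 with an estimated correlation), 2 of 18 by single gene. Ddit3 rose by 0.85 ± 0.21 and Sesn2 by 0.72 ± 0.18, the first with an adjusted p of 0.0586 without obesogenic replicate 1 and 0.0534 without obesogenic replicate 5. Sesn2 lost its call in 5 of the 13 fits without 1 library. The list was at 0.0696 without control replicate 6 and at 0.718 with the trophoblast score.

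Fatty acid uptake and oxidation genes did not pass (median 0.14, camera adjusted p = 0.0945). Of 22, 2 rose: Lpl, which encodes lipoprotein lipase, by 1.7 ± 0.39 and Pdk4 by 1.37 ± 0.36. Lpl had an adjusted p of 0.0504 without control replicate 3 and 0.0611 without obesogenic replicate 1, and Pdk4 lost its call in 10 of the 13 fits. With the preset correlation the list passed as higher without control replicate 1 (0.0318), obesogenic replicate 1 (0.0366) or obesogenic replicate 5 (0.0388), and over all libraries its adjusted p = 0.618 with an estimated correlation. None of 16 fatty acid synthesis genes was called (median -0.06, camera adjusted p = 0.713), with Fasn at -0.35 ± 0.18. Insulin and IGF signalling genes did not pass (camera adjusted p = 0.862, upward, with a negative median of -0.07 and mean of -0.05). Igf2r rose by 0.80 ± 0.14 and Slc2a4, the insulin-responsive glucose transporter gene, fell (-1.83 ± 0.37), while Lepr was at 0.32 ± 0.21. In the oxidative stress list (median -0.19, camera adjusted p = 0.668), 1 of 17 rose and 2 fell: Gpx3, a secreted peroxidase gene, by 1.18 ± 0.25, Slc7a11 by -0.89 ± 0.24 and Srxn1 by -0.51 ± 0.14. Slc7a11 and Srxn1 each lost the call in 10 of the 13 fits. Hypoxia and glycolysis genes had 1 of 20 called, Adm, which encodes adrenomedullin, higher by 1.20 ± 0.24 (median -0.01, mean 0.09, camera upward at an adjusted p of 0.713).

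Cell cycle genes were lower as a list (median -0.56, camera adjusted p = 0.00015; adjusted p = 0.643 with an estimated correlation), with none of 23 called singly. Ccnb2 was at -0.89 ± 0.32, and the list had an adjusted p of 0.000237 with the trophoblast score and the preset correlation. Of 19 circadian clock genes none was called (median 0.09, camera adjusted p = 0.308), with Per1 at -0.03 ± 0.11 (between -0.08 and 0.03 with 1 library left out) and Arntl at -0.28 ± 0.20. Immediate early genes did not pass (median -0.08, mean -0.02, camera upward at an adjusted p of 0.805). Atf3, the 1 of 16 called, was at 0.57 ± 0.15 and lost its call in 9 of the 13 fits. None of 7 tested adipocyte markers was called (median -0.32, camera adjusted p = 0.668), with Pnpla2 at -0.34 ± 0.16. The other members of this list of 14 did not pass the count filter and are not in that median. Among them, Adipoq had 501 counts summed over control libraries, 500 of them in control replicate 2, and 9 over obesogenic libraries. Cfd had 1631, 1628 of them in control replicate 2, and 47.

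**Figure D3:**
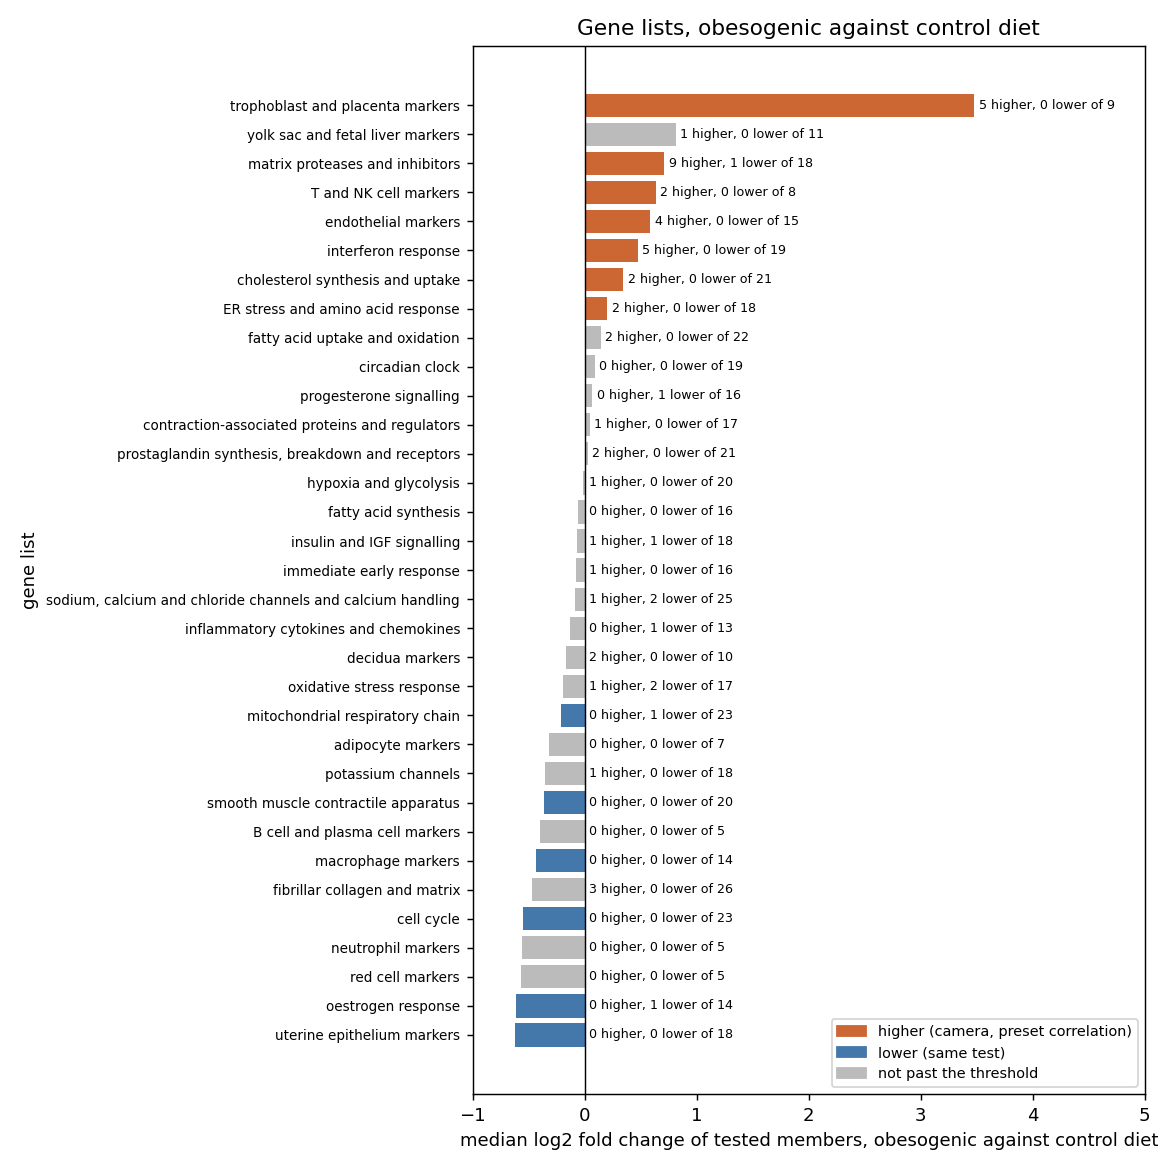
Median log2 fold change of the tested members of each of the 33 tested gene lists (horizontal axis, obesogenic against control diet), coloured orange where camera with a preset correlation called the list higher, blue where it called it lower and grey otherwise; the text beside each bar counts members called singly. The trophoblast list stands furthest out at 3.48, and 7 lists are higher and 6 lower.

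Camera called 7 lists higher and 6 lower of 33 with its preset correlation, and 0 with an estimated one, so list calls rest on that setting. With the trophoblast score in the model edgeR called 0 genes at an adjusted p under 0.05, with 756 at an unadjusted p under 0.05 against 3843 without it.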

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

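The splits of the libraries, the thinning, the fit with the trophoblast score as a test of diet, and the test of Y-linked reads were chosen after the result was seen; the shared movement with that score and the 3 tests of yolk sac markers were written down first. Of 406 groups of values examined, 25 had a library standing apart from the rest of its diet group by Dixon's test, where chance alone gives about 1 in 20. Each is given as log2 CPM with the library that stood apart.

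Several stood apart in obesogenic replicate 6, in uterine muscle genes. The smooth muscle list averaged 8.31 there, the potassium channels 2.75 and the sodium, calcium and chloride channels 4.57, each the lowest of its group. Plcb1 (2.13) and Ppp1r12b (6.7) were low in the same library, while the decidua list (5.59) and Junb (6.36) were highest. Leaving this library out ended the smooth muscle list call, as the report gives. In control replicate 6, Pgr (9.54) and Ednra (6.56) were highest and C3 (12.6) lowest. Control replicate 1 had the highest Lcn2 (11.3) and Ltf (12.2), both of uterine secretion and neutrophils, and the lowest Jchain (1.35). Control replicate 7 was highest for Slco2a1 (8.45), Igf2r (8.35) and Cubn (5.59). Control replicate 2 was highest for Thrsp (4.15) and lowest for Ppard (4.66), and control replicate 3 highest for Il1a (6.24). In obesogenic replicate 1, Alox12e (-2.72), Kcnq4 (0.279) and Cacna1d (2.52) were lowest. Obesogenic replicate 5 was highest for Prl2a1 (8.93) and lowest for Pnpla2 (5.7), and obesogenic replicate 2 highest for Gpx1 (9.65).

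The first pattern is the 1110 genes called between the diets. As many higher genes arose in 1 of 100 splits of the 13 libraries, the real one with 791 (highest other split 30). As many lower genes arose in 1 of 100, the real one with 319 (highest other 0). Chance is therefore unlikely for both, though 1 in 100 is the smallest share this number of splits can give. The test takes the libraries as separate animals, which the labels do not state. For the number of lists called chance stays open: 9 of 100 splits called at least the 13 of the real one, and the highest other split called 16. Library totals differed by -0.442 M (exact p = 0.645), and 76.3% of the called genes were still called with every total thinned to the smallest, which argues against a difference in totals as the whole cause; other aspects of depth were not matched. What stays open is whether a larger share of tissue from the maternal-fetal interface, or the diet acting on uterine cells, may account for them: 86.1% of called genes outside the trophoblast list moved with the trophoblast score within the diet groups as between them, but 4 of 100 permutations did as well (highest 88.9%). The share was 92.7% among higher and 69.6% among lower genes, and 76.9% in control and 86.4% in obesogenic libraries alone, each with 10 of 100 permutations as high. With that score in the model edgeR called 0 genes (756 at unadjusted p under 0.05), where the median size fell from 0.982 to 0.592 and the median SE grew from 0.212 to 0.369.

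The second pattern is yolk sac markers high in control replicate 7 and obesogenic replicates 3 and 4. Afp reached 3500 to 5470 CPM there against at most 741 elsewhere, and Apoa1 924 to 1570 against 203. Rbp4, the 1 gene of the list called between the diets, did not follow this pattern, at 197 to 381 CPM against up to 630 elsewhere. Visceral yolk sac tissue carried over may be the source: all 4 endocytic genes (Cubn, Amn, Lrp2 and Dab2) were higher in each of the 3 libraries than in every other. Cubn and Amn belong to the list by which these libraries stood apart, so for them this follows from the choice. Outside the list, Lrp2 was at 184 to 267 CPM against at most 40.4 elsewhere, and Dab2 at 359 to 467 against 245. For fetal liver, 0 of the 4 hepatocyte genes in the table (of 7 named in advance) were higher in this way. That cannot decide against fetal liver, since Arg1, Tdo2 and Cyp2e1 reached 21.3, 17.1 and 81.8 CPM in other libraries. Tdo2 is also in the decidua list. Cps1 was at most 0.458 CPM in the 3 libraries, and Cyp2e1 was at 0 CPM in all 3. Whether control replicate 7 is an obesogenic library under a wrong label was not settled. It lay nearer the obesogenic mean for 43.9% of the genes called without it, against at least 73.5% for every obesogenic library and at most 32.3% for the other controls. By the rule set in advance this argues against a wrong label, but the value lies between the groups. Correlations of its log2 CPM were 0.969 and 0.958 with obesogenic replicates 3 and 4, which share its high yolk sac markers. With obesogenic replicates 1, 2, 5 and 6 they were 0.8367, 0.8837, 0.8395 and 0.8925. Among controls they ran from 0.8755 with control replicate 1 to 0.914 with control replicate 5. The 2 high values cannot be told apart from the shared yolk sac pattern, so they do not decide on the label.

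The last pattern is Y-linked reads in this female organ. Obesogenic replicates 5 and 6 had 128 and 52 Y-linked counts, above the 37 of control replicate 6, the highest control, and the other 10 had at most 8. Male fetal tissue carried over may be the source: all 4 Y-linked genes had reads in each of these 3 libraries. The sex of the fetuses is not in the labels, so female fetal tissue elsewhere stays open.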

How the results depend on the processing

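Tests chosen after the results were seen are those without the 3 libraries high in yolk sac markers, with the decidua or yolk sac score in the model, and after thinning to the smallest total; the other alternatives were planned. DESeq2 called 1176 genes higher and 700 lower, limma voom 886 and 516, and a threshold of 0.1 gave 1123 and 671, against 791 and 319. Under the trophoblast score edgeR called 0 higher and 0 lower (756 at unadjusted p under 0.05), with 2 lists higher and 3 lower. That score differs by diet for 69.6% of its variance, which inflates the variance of the diet term 3.29 times, and 1102 of the 1110 called genes kept their sign. Without control replicate 1 and obesogenic replicate 1, the 2 libraries titled in another number series, there were 438 and 176 genes. Leaving out obesogenic replicate 1 alone gave 431 and 137, and control replicate 1 alone 773 and 353. The fit without the 3 libraries high in yolk sac markers gave 844 and 178. With the decidua score there were 300 and 158, with 4 lists higher. With an estimated correlation 0 lists were higher and 0 lower. Of the 1110 called genes, DESeq2 also called 1110, limma voom 1012, RLE scaling 1104, upper-quartile scaling 1060, the fit without a filter 860, the stricter filter 1058, the surrogate variable 1061, the yolk sac score 1066, the thinned counts 847, the fit without the 3 libraries high in yolk sac markers 789, the fit without the 2 libraries of another number series 545, the decidua score 404 and the trophoblast score 0.

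Directions turned as follows, none of them for a named gene that passed the test. Trophoblast score in the model: genes Oxtr 0.60, Ptgfr 1.32, Pgr 0.065, Kcnma1 0.39, Kcnt2 -0.066, Arntl 0.044, Plcb1 0.19, Ppp1r12b 0.028, Cnn1 0.11, Cited2 -0.34, Kcnq4 0.0072, Slco2a1 -0.052, S100a8 2.05, Csf3r 1.21, Ltf 1.06, Car9 0.26, Bnip3 -0.039, and lists (camera adjusted p) smooth muscle contractile apparatus 0.718, progesterone signalling 0.603, sodium, calcium and chloride channels 0.483, inflammatory cytokines and chemokines 0.484, interferon response 0.718, neutrophil markers 0.483, hypoxia and glycolysis 0.541, insulin and IGF signalling 0.718, decidua markers 0.947, yolk sac and fetal liver markers 0.175. Without the 2 libraries titled in another number series: genes Oxtr 0.16, Ptgfr 0.29, Per1 0.017, Ltf 0.57, Lipe 0.014, and lists (camera adjusted p) insulin and IGF signalling 0.867, red cell markers 0.873. With the decidua score: genes Oxtr 0.66, Ptgfr 0.57, Pgr 0.054, and lists (camera adjusted p) sodium, calcium and chloride channels 0.653, hypoxia and glycolysis 0.287. By limma voom: genes Ptgfr 0.61, S100a8 0.16, Alas2 0.19, Hba-a1 0.23, Hbb-bs 0.31, Hba-a2 0.47, and lists (camera adjusted p) hypoxia and glycolysis 0.863, red cell markers 0.599. Without the 3 libraries high in yolk sac markers: genes Pgr 0.012, Kcnt2 -0.19, Cubn -0.29, Alb -2.73, and lists (camera adjusted p) immediate early response 0.999, yolk sac and fetal liver markers 0.0172 (the list these libraries were chosen by, so its turn follows from the choice). Under upper-quartile scaling: genes Kcnt2 -0.00058, and lists (camera adjusted p) red cell markers 0.999. With 1 surrogate variable: genes Kcnt2 -0.0049, and lists (camera adjusted p) yolk sac and fetal liver markers 0.978. With the yolk sac score: genes Kcnt2 -0.022. By DESeq2: lists (camera adjusted p) immediate early response 0.936, insulin and IGF signalling 0.813. After thinning: lists (camera adjusted p) inflammatory cytokines and chemokines 0.983. Without a count filter: lists (camera adjusted p) B cell and plasma cell markers 0.602, insulin and IGF signalling 0.937.

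Leaving out each library in turn gave 431 to 913 genes higher and 137 to 381 lower, 5 to 8 lists higher and 5 to 8 lower, and a difference in library totals of -0.809 to 0.00318. The fewest of both came without obesogenic replicate 1, the most higher genes without control replicate 7 and the most lower genes without control replicate 6. Of 75 called named genes, 46 passed whichever library was left out. Ranges that crossed 0 were Oxtr -0.59 to 0.20, Ptgfr -0.77 to 0.20, Kcnt2 -0.097 to 0.13, Per1 -0.083 to 0.035, Csf3r -0.62 to 0.019, Ltf -0.98 to 0.40, Pck1 -0.69 to 0.0196 and Hba-a2 -0.72 to 0.072. Lists that turned direction ran, by camera adjusted p, from 0.363 to 0.902 (sodium, calcium and chloride channels), 0.42 to 0.992 (immediate early response), 0.564 to 0.996 (inflammatory cytokines), 0.62 to 0.828 (hypoxia), 0.615 to 0.97 (insulin and IGF), 0.343 to 0.919 (yolk sac) and 0.627 to 0.995 (red cells). The cause was not tested.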

Other observations

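The tests of gene families, adipocyte genes and correlations, and the splits of the libraries, were chosen after the results were seen; the list tests under the trophoblast score and with an estimated correlation were planned. Among 399 gene families compared by shared symbol, the prolactin family stood out, with 8 of 12 tested members higher (adjusted p = 3.22e-06), among them Prl2a1, Prl7b1 and Prl7d1. H2 genes of antigen presentation had 10 of 22 higher (adjusted p = 3.22e-06), including H2-K1, H2-D1 and H2-T23 besides the H2-Q members. Serpinb genes had 7 of 14 higher (adjusted p = 0.000183), 6 of them copies of Serpinb9. The phospholipase group named Pla had 6 of 14 higher (adjusted p = 0.00273), matrix metalloproteinases 6 of 17 (adjusted p = 0.00804) and Tnfrsf receptors 6 of 18 (adjusted p = 0.0097), against 4.29% of all tested genes. Copies within a family share reads and are not independent, so these p-values are too small by an unknown amount.

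Adipocyte genes were high in 1 control library: Adipoq reached 43.6 CPM in control replicate 2 against at most 0.706 elsewhere, Cfd 142 against 3.88 and Plin1 20.9 against 0.265. Adipose tissue carried over may be the source: 10 of the 14 adipocyte list genes were highest in that library, but Lipe, Pnpla2, Plin4 and Pck1 were not. The library stood out in this same list, so the count restates the pattern and is no separate test. Uterine cells express some of the list genes, which also keeps this source open. No other explanation was tested.

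Oxtr and Gja1 ranged widely within each diet. They correlated in control libraries (r = 0.875, exact p = 0.00774, rho = 0.929, adjusted p = 0.0464 over 6 relations; 0.714 without the 2 farthest). In obesogenic libraries r was 0.721 (exact p = 0.135, rho = 0.829, adjusted p = 0.202; 0.973 without the 2 farthest). For Ptgfr in controls r was 0.372 with Oxtr (exact p = 0.419, rho = 0.286, adjusted p = 0.451; 0.0517 without the 2 farthest) and 0.689 with Gja1 (exact p = 0.0954, rho = 0.464, adjusted p = 0.191; -0.296). In obesogenic libraries these were 0.802 (exact p = 0.0292, rho = 0.829, adjusted p = 0.0876; 0.613) and 0.418 (exact p = 0.451, rho = 0.543, adjusted p = 0.451; 0.987). Whether contraction genes vary together within a diet therefore stays open, and no biological explanation was tested.

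Whether interface tissue or diet accounts for the called genes can be tested by counting trophoblast, endothelial and muscle cells in sections of such sites, or by sequencing muscle freed of the attachment area. Under the trophoblast score 2 lists stayed higher (matrix proteases and endothelium) and 3 lower (mitochondrial respiratory chain, cell cycle and epithelium), all with the preset correlation. With an estimated correlation, and without that score, none of these 5 passed (adjusted p = 0.304, 0.338, 0.618, 0.643 and 0.643), and 9 of 100 splits of the libraries, the real one included, called at least its 13 lists without the score, so they are weak grounds for choosing what to measure.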
